A study of Arabidopsis thaliana with 3 samples.

How the data were processed

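Protoplasts carrying GFP were sorted by flow cytometry from root tips of wild-type Arabidopsis thaliana (Columbia) seedlings aged 6 days, and their total RNA was profiled on Affymetrix Arabidopsis arrays. The 3 arrays form 1 group, mature endodermis, and the labels call them biological replicates. The series description names E30 as the GFP marker line. RNA was amplified in a protocol with 2 cycles and labelled with biotin, per the labels' protocols.

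The deposited values are intensity values, 1 linear signal per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5, the target of its scaling and any filter are not stated. All values lie above 0 and none is on a log scale, as checked on the table. Each array holds 22810 probe sets, of which 64 are control probe sets and were left out of every gene value. Of the 22746 remaining probe sets, the platform's annotation pairs 13513 with 1 gene and 503 with several, and does not list 8730. The unlisted probe sets are unnamed here and were counted but not named. Of the 13513 probe sets, 13436 matched a locus of the TAIR10.1 annotation, which was used only for names. A gene's value is the mean of its probe sets' log2 signals. No gene was named from a probe set that lists several.

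The annotation covers 41 of the 290 genes in 21 lists written from general knowledge before the data were examined. For 5 of those lists, suberin, nutrient transport, root cap, seed and flower, no member was measured under a name. A further 25 lists were added from the genes that the annotation names, before the values of those genes were seen. Signals were log2 transformed as deposited, with no further scaling.

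A probe set was called detected when its signal exceeded, on each of the 3 arrays, the 95th percentile of the probe sets of genes of pollen, seed and flower. Only 5 such probe sets were measured, all from the pollen list, so this threshold rests on few values. A list of at least 3 genes was given the percentile of its median among 10000 random lists of the same size drawn from all genes. For the shift of a list between arrays, each gene's log2 signal on an array was set against the mean of the other 2 arrays. The median shift of a list of at least 2 genes was placed among 10000 random lists matched on signal in 20 bins, and it was called shifted outside the 2.5th to 97.5th percentile. These percentiles describe the 3 arrays and are not p-values. The barrier list (the measured Casparian strip genes) was compared with 8 of 11 planned lists by a two-sided exact permutation test over genes of the difference of medians, with Benjamini-Hochberg adjustment over the 8. Genes were permuted, which are not replicate samples.

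A fixed rule set which genes could be named, and not all of these are printed. It takes all measured members of the lists for the Casparian strip, suberin, the SHR and SCR pathway, and HD-ZIP III and AGO. From every other list it takes the detected members where they are 4 or fewer and otherwise the first 4 in written order (alphabetical for added lists). It also takes the 10 detected probe sets with the largest range over the arrays and the 10 members of the first 21 lists with the largest range. Names outside this rule are given as chosen after their values were seen. Where a list name from general knowledge differs from the annotation, the locus is given.

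Alternatives were scaling each array to the same median, quantile normalization, an offset of 16 added before the log2, inclusion of probe sets with several genes, omission of each replicate in turn, other detection thresholds, detected probe sets only, and a difference of means in the tests. Thresholds from 27 Bacillus control probe sets and from a list of 33 reproductive and stomatal genes were chosen after seeing the data or the annotation. The published profiles of other cell types named in the series description were not used here, and there is no second group, so no test between groups was made. The number of arrays limits the precision.

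The list steps were tested on simulated data for 13355 genes, drawn from the real means and spreads. With no change, lists of 3, 10 and 25 genes were called shifted in 1%, 8% and 4% of 100 simulations. A change of 0.5 on the log2 scale in 1 array was called in 27%, 83% and 100%, and a change of 1 in 70%, 100% and 100%. For the level of lists of these sizes, calls with no change came in 3.5%, 5% and 5.5% of 200 simulations. A level raised by 2 on the log2 scale was called in 19%, 57.5% and 90%, and by 4 in 57%, 98.5% and 100%. A raised level was thus often missed in lists of 3 genes. Genes of 1 list can vary together on an array, and these rates do not cover that case. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.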

Results

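Transcript signals were measured in mature endodermis cells sorted from roots of 6-day-old wild-type seedlings, on 3 arrays from biological replicates. The study set this profile beside published profiles of other root cell types to follow the targets of the transcription factors SHR and SCR. The median signal of the 22746 gene probe sets was 55.1, 53.3 and 64.7 on replicates 1, 2 and 3. Signals are in arbitrary units throughout, and errors are SD over n = 3 arrays. The ratio of 3' to 5' signal of 5 control pairs lay between 2.24 and 17.1, so signals favoured the 3' end on every array. This limits every signal level and detection call below.

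Genes of the Casparian strip, the lignified barrier of the endodermis, gave strong signals on every array. The peroxidase gene PER72 (AT5G66390) had a signal of 10231 ± 706. SGN1 (AT1G61590), which encodes a kinase, had 7221 ± 1649, and the receptor kinase gene GSO1 (AT4G20140) had 4771 ± 1229. The median log2 signal of these 3 genes was 12.79 ± 0.32, higher than in all 10000 random lists of 3 genes. Those lists were drawn from genes whose probe sets had a lower median signal than the unlisted ones, as given below. The lignin pathway gene HCT (AT5G48930) had a signal of 6385 ± 1499. The other 9 genes written for the Casparian strip, and the suberin list, are unnamed in the annotation and were not analysed here.

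Genes of other root cell types were compared with the barrier genes to ask what else the sorted cells expressed. The 3 cortex genes were not detected on all arrays. AT1G62510 had signals of 4.13, 57.3 and 7.89, AT1G62500 had 12.2, 28.7 and 10.6, and AT1G09750 had 12.3, 4.05 and 4.02. AT1G62500 was named after its values were seen. The phloem gene OPS (AT3G09070) gave 14.7 ± 8.59 and was above the threshold on 1 array. Genes of the pericycle list were detected on all 3 arrays, LBD16 (AT2G42430) at 1022 ± 160 and LBD29 (AT3G58190) at 96.8 ± 3.94. The xylem gene LHW (AT2G27230) had 134 ± 20.9.

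The barrier list was higher than each of 8 other lists on all 3 arrays, by 4.50 on the log2 scale over the pericycle and xylem loading list, 5.74 over xylem, 5.97 over meristem and cell cycle and 6.16 over photosynthesis. Where other genes lay below the background threshold they were set to it, which gives differences of at least 6.74 over epidermis, 8.17 over cortex and 8.33 over phloem. No gene of the cortex and phloem lists was detected on all arrays. No size is given for the pollen list, since its genes set the threshold. The tests used the measured values. None passed a two-sided exact permutation test over genes after adjustment. The smallest exact p was 0.0536 (adjusted 0.214) for the meristem and pollen lists of 5 genes each, which is the smallest that 3 genes against 5 gave under any split. The exact p was 0.1 for pericycle, 0.2 for cortex, epidermis and photosynthesis, and 0.25 for xylem and phloem, with adjusted p of 0.25 in each. With 1 to 5 genes in each other list, these tests of medians could not reach 0.05, and single probe sets also differ in how strongly they bind.

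**Figure D1:**
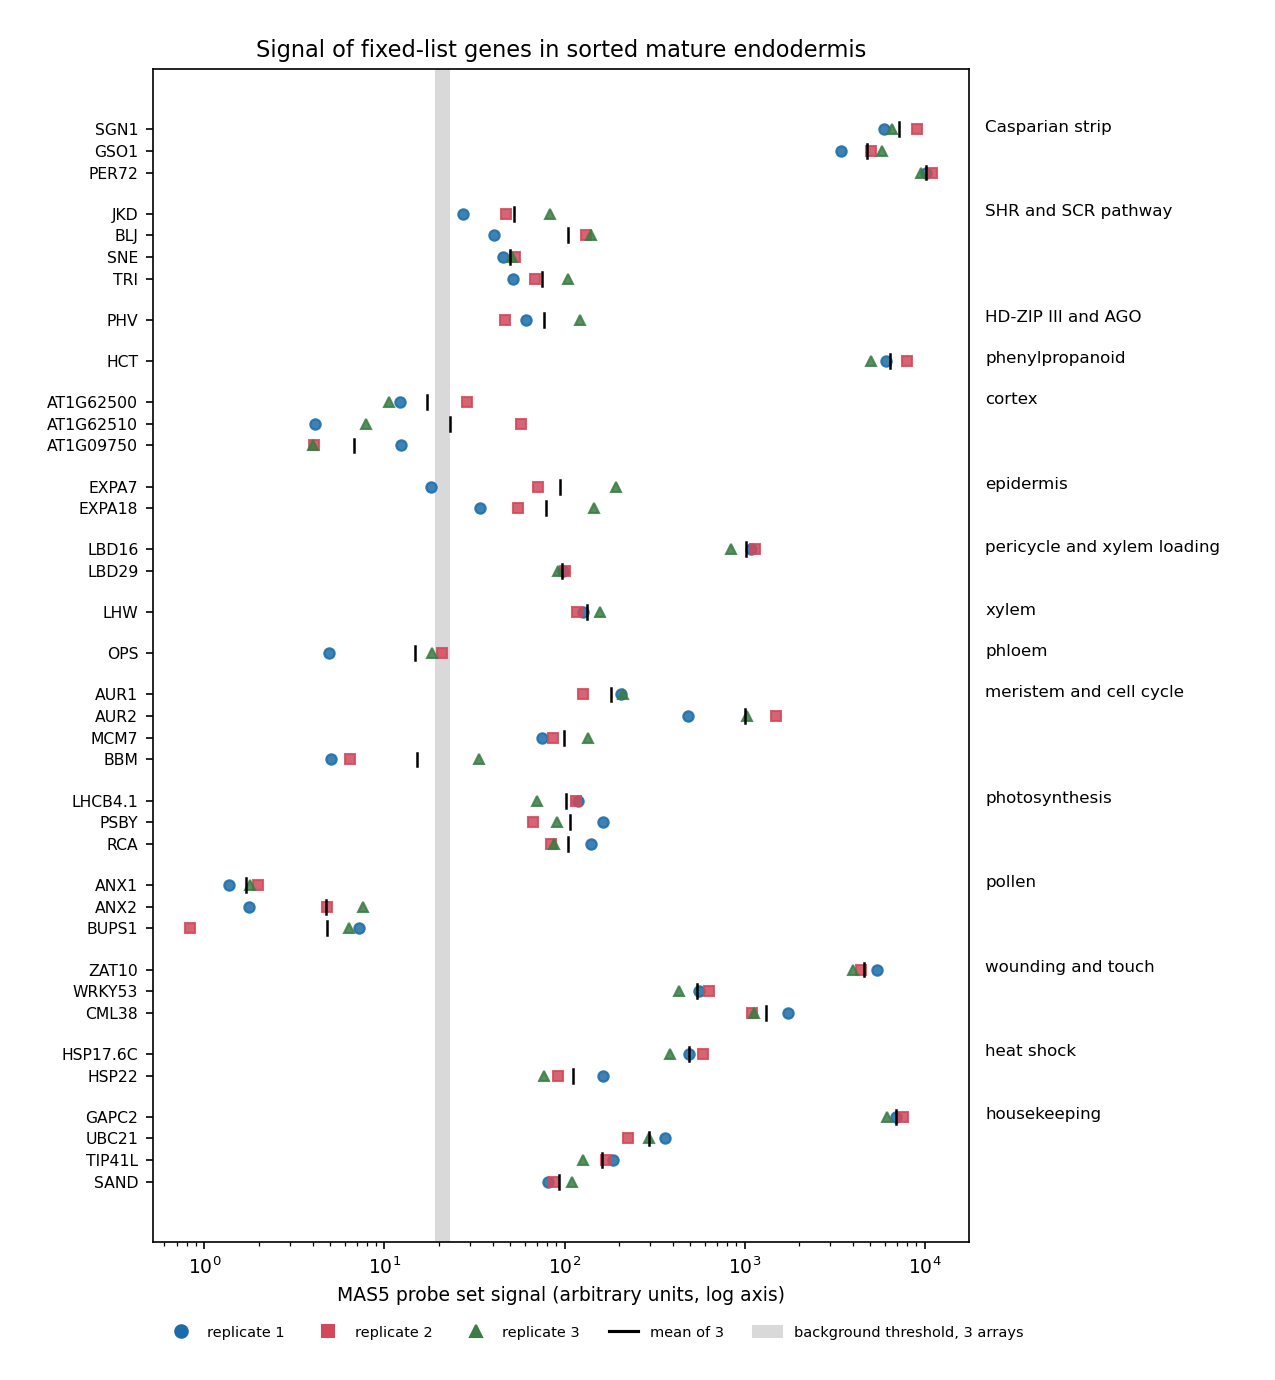
Signal of measured genes of 15 gene lists (points, replicates 1 to 3; vertical line, mean of 3 arrays) on a log axis in arbitrary units, with the span of the background thresholds in grey. The Casparian strip genes lie between 3421 and 10978, and the 3 cortex genes between 4.02 and 57.3.

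Genes of the SHR and SCR pathway gave weak signals that were above the main threshold on all 3 arrays. JKD (AT5G03150) had 27.2, 47.2 and 82.8 on replicates 1 to 3, and BLJ (AT1G14580) had 40.5, 132 and 140. SNE (AT5G48170) had 49.9 ± 4.02 and TRI (AT2G29330) had 74.8 ± 27.0. The median of these 4 genes lay at the 61.4th percentile of random lists. PHV (AT1G30490), the 1 measured gene of the HD-ZIP III and AGO list, had 61.0, 46.8 and 122. None of these 5 genes passed the higher threshold from reproductive and stomatal genes on all arrays. SHR, SCR, PHB, REV and AGO1 are unnamed in the annotation and were not analysed here.

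The background threshold was 22.8, 19.3 and 22.7 on the 3 arrays, and 8108 of 13513 probe sets with 1 gene (60.0%) were above it on all of them. They stand for 8053 genes. The count was 8454 with the Bacillus control probe sets as background and 4758 with the reproductive and stomatal genes, whose threshold was 66.8, 69.3 and 71.7. The highest of the 5 pollen genes on each array exceeds the main threshold by construction, and 2 different genes did so over the arrays.

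Of the 20 genes written for wounding and touch, the 3 that were measured were strong in these protoplasts. ZAT10 (AT1G27730) had 4605 ± 741, CML38 (AT1G76650) had 1322 ± 359 and WRKY53 (AT4G23810) had 541 ± 104, and their list lay at the 99.7th percentile. The small heat shock protein genes HSP17.6C (AT1G53540) and HSP22 (AT4G10250) had 491 ± 102 and 111 ± 46.7. Reference genes had 6909 ± 713 for GAPC2 (AT1G13440), 293 ± 68.2 for UBC21 (AT5G25760), 161 ± 30.4 for TIP41L (AT4G34270) and 92.8 ± 15.3 for SAND (AT2G28390). DFR (AT5G42800), of the flavonoid pathway, had 37.1 ± 17.7.

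Of the 26 genes of the cell division list, 18 were detected and 8 were not, against 60.0% of all probe sets with 1 gene. AUR1 (AT4G32830) had 181 ± 47.0, AUR2 (AT2G25880) had 1004 ± 508 and MCM7 (AT4G02060) had 98.8 ± 31.7. BBM (AT5G17430) was above the threshold on 1 array, with 5.04, 6.47 and 33.7. The nuclear photosynthesis genes LHCB4.1 (AT5G01530), PSBY (AT1G67740) and RCA (AT2G39730) had 101 ± 27.0, 107 ± 49.9 and 104 ± 31.9.

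Among 33 lists with at least 3 measured genes, 13 had a median outside the middle 95% of random lists. The random lists hold only genes with a probe set of 1 gene. The median signal of those probe sets was 46.6, against 81.0 for the unlisted ones. For 88.0% of the probe sets with 1 gene the symbol was only the locus name. The percentiles were not corrected for either point. The plastid-encoded list (69 genes, among them atpE at 7916 ± 351 and atpB at 2996 ± 542) was above all random lists. So were the lists for respiration, autophagy (APG8H 1912 ± 548, APG8A 638 ± 50.3), ESCRT (VPS2.1 1661 ± 184, SNF7.2 208 ± 53.3) and extended wounding and touch genes. The respiration list of 18 genes also holds genes of ATP-citrate lyase, a cytosolic enzyme (ACLA-1 2844 ± 247, ACLA-3 2061 ± 426). It was not split, so its level is not that of respiratory genes alone. The mitochondrion-encoded list lay at the 99.9th percentile, iron and zinc regulation (ILR3 1383 ± 493, PYE 153 ± 30.4) at the 99.4th, and lignin and coumarin at the 99.0th. Among the lists on the low side, the reproductive and stomatal list lay at the 0.4th percentile (0.05th without replicate 3) and pollen at the 0.985th. The pollen list moved to the 2.59th percentile without replicate 1 and to the 2.84th without replicate 2, back inside the middle 95%. The number of lists outside it was 13 or 14 when a replicate was left out.

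The 3 replicates were close over all probe sets. Pearson's r of log2 signal across the 22746 probe sets was 0.924, 0.931 and 0.930 for replicates 1 and 2, 1 and 3, and 2 and 3, and Spearman's rho was 0.945, 0.951 and 0.953. Probe sets are not independent replicates. The median SD of a probe set's log2 signal was 0.31. A range of at least 2-fold was found in 1339 detected probe sets (16.5%), with the highest array being replicate 1 in 395, replicate 2 in 289 and replicate 3 in 655. The share depended on the processing and was 9.37% with the offset of 16.

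The largest range among detected probe sets, 4.32 on the log2 scale, was that of AT1G65500, with 420, 21.0 and 27.4 on replicates 1 to 3. Replicate 1 was also highest, and replicate 2 lowest, for AT2G47550 (a 9.59-fold range), AT1G19530 (260, 29.9 and 49.9), AT5G16010 (3353, 403 and 939), AT5G52670 (446, 62.4 and 160), AT1G49570 (462, 65.4 and 75.5) and AT5G28630 (762, 113 and 440). Replicate 3 was highest for GH9C1 (AT1G48930; 28.3, 49.5 and 206) and AT1G30870 (52.3, 243 and 361). The plastid gene psbA had 1386, 3660 and 428.

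Genes of the SHR and SCR pathway were lower in replicate 1 than in the others, with a median shift of -0.95 on the log2 scale (0.09th percentile of matched lists, 4 of 4 genes lower) and of -0.60 without replicate 3. In replicate 3 the list was higher by 0.88 (99.4th percentile), but without replicate 1 the shift was 0.35 (66.1th percentile) and was no longer called. The endoplasmic reticulum body genes were also lower in replicate 1, by a median shift of -0.92. Among them NAI1 had 58.2 ± 16.0 and was lowest in replicate 2, not replicate 1. NAI2 had 99.9, 298 and 300, JAL33 had 213, 313 and 443, JAL34 had 478, 833 and 983, and PYK10, chosen after its values were seen, had 1261, 2712 and 3142. The epidermal genes EXPA7 (AT1G12560; 18.0, 71.5 and 192) and EXPA18 (AT1G62980; 34.1, 54.9 and 147) shifted by -2.05 in replicate 1 (-1.34 without replicate 3) and by 2.09 in replicate 3. Tubulins and actins shifted by -0.56 in replicate 1 and the 5 meristem genes by -0.77. Without replicate 3 these shifts were -0.44 and -0.36, and neither was called. The list of 26 cell division genes, which holds AUR1, AUR2 and MCM7, shifted by -0.12 in replicate 1 and was not called.

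Other lists were higher in replicate 1. Sugar transporter genes of the SWEET family shifted by 0.53, with SWEET11 at 1676, 409 and 582 and SWEET16 at 178, 74.6 and 148. SWEET13 was highest in replicate 3, with 49.7, 37.0 and 52.8. Without replicate 2, the SWEET list shifted by 0.10 in replicate 1 and was no longer called. The 3 photosynthesis genes shifted by 0.72. The list of 24 nuclear photosynthesis genes that holds them shifted by 0.23, which was no longer called without replicate 3 (0.097) or over detected probe sets (0.10). Autophagy genes shifted by 0.41, the 69 plastid-encoded genes by 0.33 and extended wounding and touch genes by 0.40. Of 36 lists, 15 were called in replicate 1 (9 higher, 6 lower), 8 in replicate 2 (2 higher, 6 lower) and 7 in replicate 3 (4 higher, 3 lower). The median gene shifted by -0.05, -0.06 and 0.16 on replicates 1 to 3, and the matched lists carry the same offset. Between replicates 2 and 3 alone, each list gives 2 shifts that mirror each other, and 12 of these 72 were called. With 1 array set against 2 of the same group, no shift has a replicate check.

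**Figure D2:**
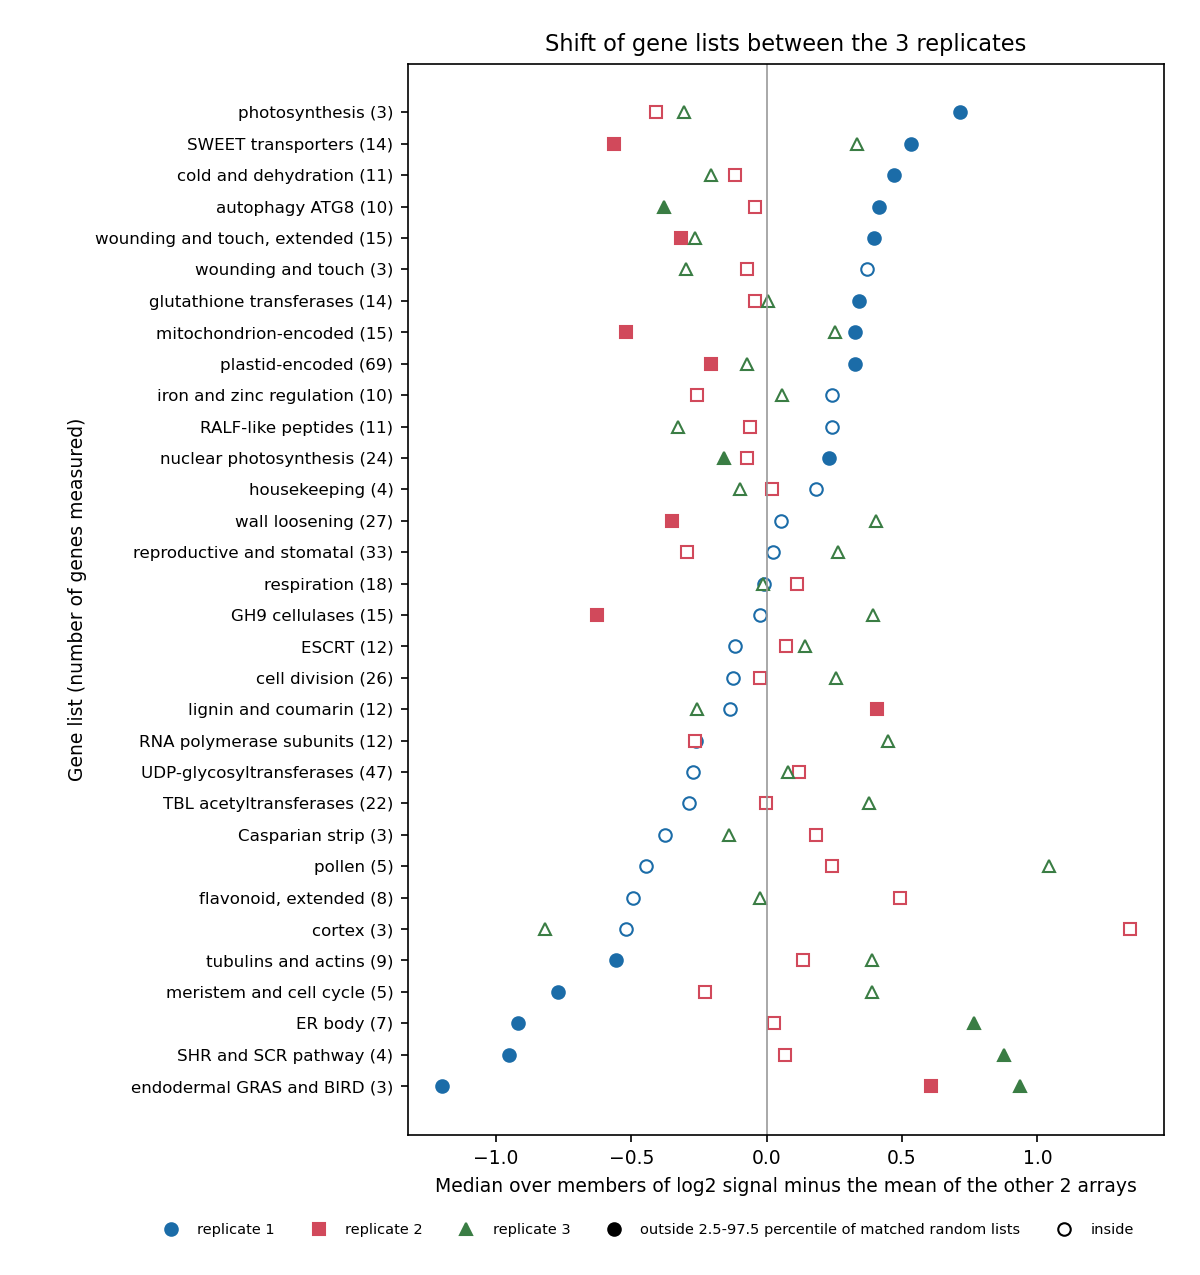
Median shift of gene lists with at least 3 measured genes on each replicate (log2 signal minus the mean of the other 2 arrays), with filled symbols outside the middle 95% of matched random lists. Replicate 1 has filled symbols on both sides, from endodermal GRAS and BIRD genes at -1.20 to photosynthesis genes at 0.72.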

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

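The choice to look at the probe sets that the annotation does not list was made after seeing the data. Of these 8730 probe sets, 6273 (71.9%) gave a signal above the main threshold on all 3 arrays, although no named gene stands for them in the report. This share was higher than the 60.0% among probe sets with 1 gene. Their median signal over the arrays was 81.0, against 46.6 for the probe sets with 1 gene. No biological explanation was tested for this difference.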

How the results depend on the processing

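The thresholds from Bacillus control probe sets and from reproductive and stomatal genes, and the added lists, were chosen after the data or the annotation were seen. The 8 barrier comparisons kept their direction in the 7 alternatives run that move any of their values. With a difference of means, the smallest exact p was 0.0179 (adjusted 0.0714), for the meristem and pollen lists. Lists of this size could not pass after adjustment, so the tests say nothing about stability. A comparison with the suberin list alone and those with root cap, seed and flower were not run, because no member was measured under a name.

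The count of detected probe sets fell to 5342 with the array median as threshold and to 4758 with reproductive and stomatal genes, all of them among the 8108. The lowest pairwise correlation was 0.961 with an offset of 16 and 0.946 over detected probe sets, and it ranged from 0.924 to 0.931 when a replicate was left out. The share of detected probe sets with a range of at least 2-fold was 15.7% with arrays scaled to the same median, 14.1% after quantile normalization and 9.37% with the offset. It was 13.0% with the array median as threshold and 12.6% with reproductive and stomatal genes, and ranged from 6.67% to 7.99% when a replicate was left out, where 2 arrays instead of 3 enter the range. For the other changes the cause was not tested.

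Of the 30 called list shifts, 30 stayed called with arrays scaled to the same median, 27 after quantile normalization, 28 with the offset, 30 with probe sets of several genes and 22 of 28 over detected probe sets. Leaving out replicates gave 12 to 27 calls, the lowest without replicate 1, with each list's 2 shifts mirroring each other. Without replicate 1, 5 of 15 evaluated calls were kept, 8 were lost, and 2 were lost with a change of the raw sign. The endodermal GRAS and BIRD list in replicate 2 ranged from -0.082 to 0.86 when a replicate was left out, and the nuclear photosynthesis list in replicate 3 from -0.24 to 0.064. Without replicate 1 these shifts lay at the 64.5th and 10th percentile of matched lists, against the 99.0th and 0.06th over all arrays. Each stayed on the same side of the middle of matched lists, so neither reversed relative to them. The cause of the lost calls was not tested. Without replicate 2, 18 of 22 were kept, and without replicate 3, 15 of 23. No paired analysis was possible because the series has 1 group. Signals near the threshold, as for cortex and pollen genes, limit what can be said of weak transcripts.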

Other observations

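All tests in this part were chosen after the patterns were seen, although the prediction for root hair genes was written before their values were looked at. The bound for the RNA integrity test was changed after its value was known.

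EXPA7 and EXPA18, which are expressed in root hair cells, were highest in replicate 3. Scaling of the arrays is argued against, because the smaller of the 2 shifts was still 1.54 on the log2 scale after quantile normalization. Noise of dim probe sets was not tested separately and stays open. EXPA18 was above the main threshold on all 3 arrays, and EXPA7 on 2. Root hair cells in the replicate 3 sort may contribute. Of 19 other root hair genes, 5 were measured, and their median shift in replicate 3 was 0.13, at the 63.99th percentile. The median of all genes shifted by 0.16 in replicate 3, and only EXPB5 (45.2, 25.1 and 45.0) and HRGP1 (227, 202 and 407) exceeded that. The most abundant were CSLD2 (985, 1066 and 1048) and SCN1 (563, 511 and 585), and XTH26 was below the threshold on every array. These values do not decide it, since CSLD2 and SCN1 were strong on every array and a small share of hair cells would be hidden. A sort on GFP is meant to remove cells that lack the marker, but its purity was not assessed here. No other biological explanation was tested.

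Gene lists shifted both ways in replicate 1. All 15 called lists, 9 higher and 6 lower, kept their call after quantile normalization. Random lists matched on signal carry the same scaling offset, so this outcome was largely fixed and is no separate evidence about scaling. Random lists of the same sizes gave a median of 2 calls and at most 7 in 10000 sets, against 15 of 36 lists in replicate 1. This argues against chance for lists of unrelated genes only. Genes of 1 list can vary together on an array, which random lists do not carry. Replicate 2 (2 lists higher, 6 lower) and replicate 3 (4 higher, 3 lower) were not set against random lists in this way. Some lists share genes, and 13 called lists remain when each list that shares a gene with an earlier called one is dropped. RNA integrity or amplification length could not be excluded. The ratio of 3' to 5' signal was higher in replicate 1 than in both others for 3 of 5 control pairs and lower for 1, and the largest difference was 0.73 on the log2 scale. The first bound for excluding this explanation was mixed directions with no difference of 2-fold, which these values meet. It was replaced after the values were seen by a bound that asks for nearly equal ratios, because the actin designs disagreed and the controls have no replicate spread, so the explanation stays open. A candidate explanation that was not tested is a difference in cell composition or handling between the sorts.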
